A study of Cucumis melo with 27 samples.

How the data were processed

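RNA-seq libraries were made from powdered frozen leaf and fruit tissue, with RNA extracted in Trizol, purified on columns and treated with DNase, and with cDNA made by a NuGen mRNA-seq kit, per the labels' protocols. The files deposited by the authors hold whole-number counts per gene, 1 file per library, with no normalization. STAR 2.5.4b and edgeR 3.12.1 are named in the submitters' processing notes, with no role or order. The program that counted reads, the genome build, the annotation and the treatment of strand and of reads that match several genes are not given in the sources used here. Counts of near-identical or overlapping genes are therefore uncertain.

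Each file was taken with the sample it is attached to in GEO, and each sample's group came from its title. For 12 of the 27 libraries, in 4 groups of 3, the number in the title differs from the number in the file name. Matching files to titles by library number was an alternative fixed before the data were examined, and its values are printed beside those of the attachment. None of the 27 files were identical to another (0 pairs). A planned check looked for genes at 5 CPM or more in all F39 libraries with agreeing numbers and under 0.1 CPM in the TTDV 45 d libraries, or the reverse. It found 0 such genes. With the minimum at 2 CPM, also set before the data were examined, it found 1 of each kind, and neither told the assignments apart. The F39 gene, MELO3C023027.2, reached 1 CPM in all but 1 of the 12 disputed libraries, although each assignment makes 9 of these TTDV, not the same 9. The TTDV gene, MELO3C012753.2, reached 1 CPM in 2, both in the files attached to TTDV 30-35 d, which are TTDV under both assignments.

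Counts were analysed with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 present but not called directly. Genes with low counts were removed with filterByExpr, which kept 15130 of 25200 genes, and 3500 genes had no count in any library. Libraries were scaled by TMM. A single model with 1 mean per group was fitted to all 27 libraries, and contrasts were tested by the robust quasi-likelihood F-test with Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The fruit against leaf contrast took the mean of F39 fruit at 20-25, 30-35 and 40 d. The interaction was the 40 d against 20-25 d change in TTDV minus that in F39. Fold changes are log2, and CPM values are in counts-per-million units of the library total. Named genes passed the threshold, had a mean log2 CPM of at least 3 over all libraries, had every library of the higher group above every library of the other, and were up to 2 with the largest change in each direction. A gene with no count in a group was compared with a floor of 3 counts over the group. Bounds and ratios without 1 library leave out a library of the higher group and keep the floor or counts of the lower group. For 1 to 3 counts the ratio has an exact Poisson 95% interval. Floors and intervals cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules.

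Gene lists by product name (28 lists) were fixed before the data were examined. The reference gene table, for assembly USDA_Cmelo_AY_1.0, matched 0 of the 25200 IDs, so that names could not be paired with IDs and the lists were not tested. No genome was used here.

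Rank correlations between libraries used log2(CPM + 1) of the 10472 genes with a mean of at least 5 CPM. The position of a fruit library between F39 20-25 d and 40 d was its projection, over 10195 genes chosen by the same minimum in fruit, on the line between the 2 group means. Genes separating the cultivars were those for which every fruit library of one lay above every fruit library of the other in CPM.

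The depth of 6025615 to 28731038 counts per library sets the precision of low genes. The edgeR script was tested on simulated data with 200 changed genes, 100 changed 2-fold and 100 changed 4-fold. For F39 fruit at 40 against 20-25 d, with 14722 genes fitted, it recovered 1 of the 2-fold and 30 of the 4-fold genes, with 1 false call. For fruit against leaf, with 14784 genes fitted, it recovered 15 and 59, with 3 false calls. No other gene differed between groups in the simulations, whereas 3954 and 7985 genes were called in these comparisons of the data. With so few changed genes the adjustment is stricter, so these recoveries need not hold for the data.

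Alternatives fixed before the data were examined were DESeq2 1.42.0 with its Wald test, median-of-ratios scaling in edgeR, no filter, a stricter filter (1 CPM in at least 3 libraries and a mean of 5 CPM), fits with only the groups compared, and leaving out each library in turn. A fit with only the 15 libraries whose numbers agree, the fruit mean without the 30-35 d group, and DESeq2 on the interaction by library number were added after seeing the data. Other splits of the libraries were drawn up to 100 per comparison. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.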

Results

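Transcript abundance was measured by RNA-seq in melon (Cucumis melo) grown in the field, in leaves and in fruits of 2 cultivars that the labels name F39 and TTDV. Leaves were 14 days old and came from F39. Fruits of both cultivars were harvested at 20-25, 30-35, 40 and 45 days (d) after flowering. The 27 libraries formed 9 groups of 3, and the comparisons address the difference between fruit and leaf, the course of fruit development in each cultivar, and the difference between the cultivars at each stage. Total counts per library ranged from 12912971 to 28731038 in leaf. In F39 fruit they ranged from 8507660 to 15982120 at 20-25 d, from 14797582 to 16164211 at 30-35 d, from 6500255 to 9249062 at 40 d and from 10338794 to 13964844 at 45 d. In TTDV fruit they ranged from 8854648 to 15292038 at 20-25 d, from 9137944 to 15214810 at 30-35 d, from 6025615 to 9537337 at 40 d and from 6506737 to 10196418 at 45 d. Genes are given by the IDs in the files, which carry no gene names. The labels do not say whether the 3 libraries of a group came from separate plants, so the p-values rest on the spread between libraries. That spread was estimated for each gene over all 9 groups together, not within the groups compared. The groups differed in it: the biological coefficient of variation ran from 0.376 in TTDV fruit at 40 d, as attached, to 0.767 in F39 fruit at 30-35 d. A group that varies more than the rest is thus tested with a smaller spread than its own.

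For 15 libraries the number in the sample title equalled the number in the name of the attached file. These were the leaf libraries, F39 fruit at 20-25, 30-35 and 40 d, and TTDV fruit at 45 d. For the other 12 libraries the numbers differed. The files that GEO attaches to F39 45 d carried the numbers of the TTDV 20-25 d titles, those attached to TTDV 20-25 d the numbers of TTDV 30-35 d, those attached to TTDV 30-35 d the numbers of TTDV 40 d, and those attached to TTDV 40 d the numbers of F39 45 d. Values for these groups follow the attachment in GEO. Beside each count of called genes stands the count with files matched to titles by library number. Some contrasts of the same libraries thus appear under 2 names and are not separate results. TTDV against F39 at 40 d as attached is F39 45 against 40 d by library number. TTDV 45 against 40 d as attached is TTDV against F39 at 45 d by library number. The TTDV step from 20-25 to 30-35 d as attached is the step from 30-35 to 40 d by library number.

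Fruit and leaf of F39 differed in the abundance of many genes. MELO3C012252.2 alone took 14.9% ± 0.634 (SD, n = 3) of all leaf counts and at most 0.39% in any of the 24 fruit libraries. The 10 most abundant genes held 29.4% ± 0.80 (SD, n = 3) of leaf counts, against 7.06% ± 1.44 (SD, n = 3) in F39 fruit at 20-25 d and 13.5% ± 4.0 (SD, n = 3) at 40 d. MELO3C009958.2 averaged 9432 ± 638 CPM (counts-per-million units; SD, n = 3) in leaf and 0.263 ± 0.26 CPM (SD, n = 9) over F39 fruit at 20-25, 30-35 and 40 d. MELO3C010312.2 averaged 9031 ± 2628 CPM (SD, n = 3) in leaf and 0.717 ± 1.15 CPM (SD, n = 9) in the same fruits. In the other direction, MELO3C002691.2 averaged 519.9 ± 160.7 CPM (SD, n = 9) in fruit and had no count in the 3 leaf libraries, so that it was at least 10338-fold higher in fruit. MELO3C026300.2, at 354.7 ± 96.9 CPM (SD, n = 9) in fruit and no count in leaf, was at least 7053-fold higher.

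By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, MELO3C009958.2 was lower in fruit by a log2 fold change of -16.11 (SE 1.07, adjusted p = 1.42e-10) and MELO3C010312.2 by -15.62 (SE 0.97, adjusted p = 6.25e-10), values that were -17.44 without replicate 3 of 20-25 d and -16.82 without replicate 2 of 40 d. The same edgeR test with Benjamini-Hochberg adjustment gave adjusted p = 6.45e-12 for MELO3C002691.2, adjusted p = 8.27e-13 for MELO3C026300.2 and a log2 fold change of -7.58 (adjusted p = 3.35e-08) for MELO3C012252.2. Of 15130 genes tested, 3731 were higher and 4254 lower in fruit, together 52.8%, and 2999 and 4007 of these differed by more than 2-fold. The total of 7985 became 6857, 7055 and 6801 without leaf replicates 1, 2 and 3. Across the 12 F39 libraries of leaf and of fruit at 20-25 to 40 d, 68 genes reached 1 CPM in every leaf library and stayed under 0.1 CPM in every fruit library, 32 showed the reverse, and 8765 reached 1 CPM in all 12. The median log2 fold change of all genes tested was 0.088 with TMM scaling and -0.164 with median-of-ratios scaling, which put the share of higher genes at 46.7% and 37.8% of the calls.

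F39 fruit changed widely between 20-25 and 40 d. MELO3C000113.2 had no count at 20-25 d and 71.8 ± 10.2 CPM (SD, n = 3) at 40 d, at least 887-fold higher. MELO3C018009.2 rose from 0.132 ± 0.229 to 300.8 ± 74.7 CPM (SD, n = 3 each). MELO3C015762.2 fell from 189.0 ± 60.8 CPM (SD, n = 3) to no count, at least 1461-fold lower, and MELO3C013954.2 from 48.0 ± 28.8 CPM (SD, n = 3) to no count, at least 371-fold lower. MELO3C020432.2, singled out after its values were seen because it was the most abundant gene of 9 libraries, rose from 0.092% ± 0.023 to 2.02% ± 0.463 of all counts (SD, n = 3 each), a log2 fold change of 4.75 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00104). MELO3C026550.2, also singled out after its values were seen, as the most abundant gene of 4 libraries, held 1.58% ± 0.81 of counts at 20-25 d and 0.282% ± 0.197 at 40 d (SD, n = 3 each). Its change did not pass the threshold, with a log2 fold change of -2.27 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0659).

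For the genes with the largest changes over this interval, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 1.53e-04 for MELO3C000113.2, a log2 fold change of 11.29 (SE 1.96, adjusted p = 6.83e-04) for MELO3C018009.2, adjusted p = 5.62e-04 for MELO3C015762.2 and adjusted p = 0.00679 for MELO3C013954.2. In all, 1692 genes were higher and 2262 lower at 40 d, together 26.1% of those tested, of which 1492 and 2130 changed by more than 2-fold. Without replicate 2 of the 40 d group the total of 3954 became 2594, and without replicate 1 of 20-25 d the log2 fold change of MELO3C018009.2 was 14.84.

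**Figure D1:**
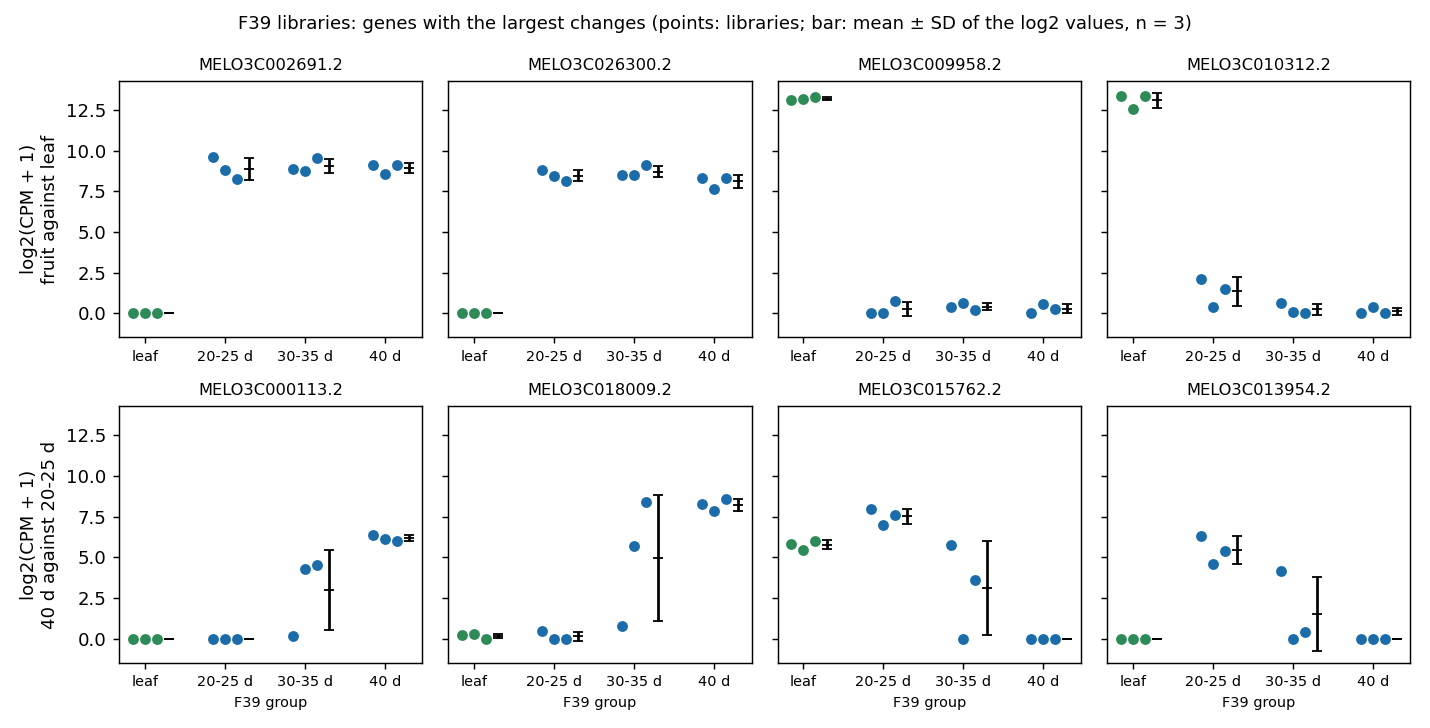
Abundance, as log2(CPM + 1), of the 4 genes with the largest changes between F39 fruit and leaf (upper panels) and of the 4 with the largest changes between F39 fruit at 40 and 20-25 d (lower panels). Points are libraries, green for leaf and blue for fruit, and the bars are the mean ± SD of the log2 values over n = 3; in the lower panels the 3 libraries of 30-35 d are spread between the levels of the earlier and the later stage.

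The 30-35 d group of F39 held libraries at different points between those stages. The transcriptome-wide position of a library was set to 0 at the mean of the F39 20-25 d libraries and 1 at the mean of the 40 d libraries, each library being left out of the mean it would enter. The 3 libraries of 30-35 d lay at 0.177, 0.954 and 0.561, whereas those of 20-25 d lay between 0.047 and 0.09 and those of 40 d between 0.825 and 1.024. MELO3C000113.2, for example, had 0.124, 18.2 and 22.3 CPM in replicates 1, 2 and 3 of 30-35 d, and MELO3C015762.2 had 53.8, 0 and 10.9 CPM. The biological coefficient of variation was 0.767 at 30-35 d, against 0.53 at 20-25 d and 0.554 at 40 d.

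The steps into and out of 30-35 d gave fewer calls. Between 20-25 and 30-35 d, MELO3C000113.2 rose from no count to 13.6 ± 11.8 CPM (SD, n = 3), at least 168-fold, with adjusted p = 0.00375 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). MELO3C027277.2 rose from a single count over the group to 72.4 ± 62.8 CPM (SD, n = 3), a ratio of 2685 (95% counting interval 482 to 106066; adjusted p = 0.00345 by the same edgeR test with Benjamini-Hochberg adjustment). MELO3C008417.2 fell from 14.9 ± 16.6 CPM (SD, n = 3) to no count, at least 227-fold, and MELO3C011860.2 from 5.47 ± 5.11 CPM (SD, n = 3) to no count, at least 83-fold, with adjusted p = 0.00798 and 0.0323 by edgeR with Benjamini-Hochberg adjustment. The call for MELO3C011860.2 was lost in 4 of 6 fits that left out 1 library, and that for MELO3C008417.2 in 1. Without replicate 1 of 20-25 d their bounds were 47-fold and 88-fold, and without replicate 3 of 30-35 d the ratio for MELO3C027277.2 was 1787. Here 634 genes were higher and 254 lower at 30-35 d. That total of 888 became 2222, 68 and 500 without replicates 1, 2 and 3 of 30-35 d, 255, 447 and 230 without replicates 1, 2 and 3 of 20-25 d, 490 with only the 15 libraries whose numbers agree, 0 with only the 2 groups fitted and 1794 with DESeq2, beside 3596 genes at an unadjusted p under 0.05.

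Between 30-35 and 40 d, MELO3C012305.2 fell from 92.7 ± 117.3 to 0.307 ± 0.164 CPM (SD, n = 3 each), a log2 fold change of -7.94 (SE 1.38, adjusted p = 0.0117 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MELO3C004098.2 fell from 22.2 ± 22.9 CPM (SD, n = 3) to a single count over the group, a ratio of 516 (95% counting interval 93 to 20376). MELO3C013519.2 rose from 13.97 ± 15.04 to 2675 ± 3175 CPM (SD, n = 3 each), a log2 fold change of 7.63 (SE 1.78, adjusted p = 0.0451 by the same edgeR test with Benjamini-Hochberg adjustment). Each of these calls was lost in at least 3 of the 6 fits that left out 1 library. The log2 fold change of MELO3C012305.2 was -6.02 without replicate 1 of 30-35 d and that of MELO3C013519.2 was 5.89 without replicate 2 of 40 d and 9.41 without replicate 2 of 30-35 d, and the ratio for MELO3C004098.2 was 239 without replicate 3 of 30-35 d. In total 32 genes were higher and 80 lower at 40 d, but more were higher than lower without replicate 1 (5 and 1), replicate 2 (14 and 8) or replicate 3 (42 and 29) of 40 d. The total of 112 became 0 and 623 without replicates 1 and 2 of 30-35 d, 6, 22 and 71 without replicates 1, 2 and 3 of 40 d, 13 with the 15 libraries whose numbers agree, 0 with only the 2 groups fitted, 70 without the filter on low counts and 740 with DESeq2, beside 2324 genes at an unadjusted p under 0.05.

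**Figure D2:**
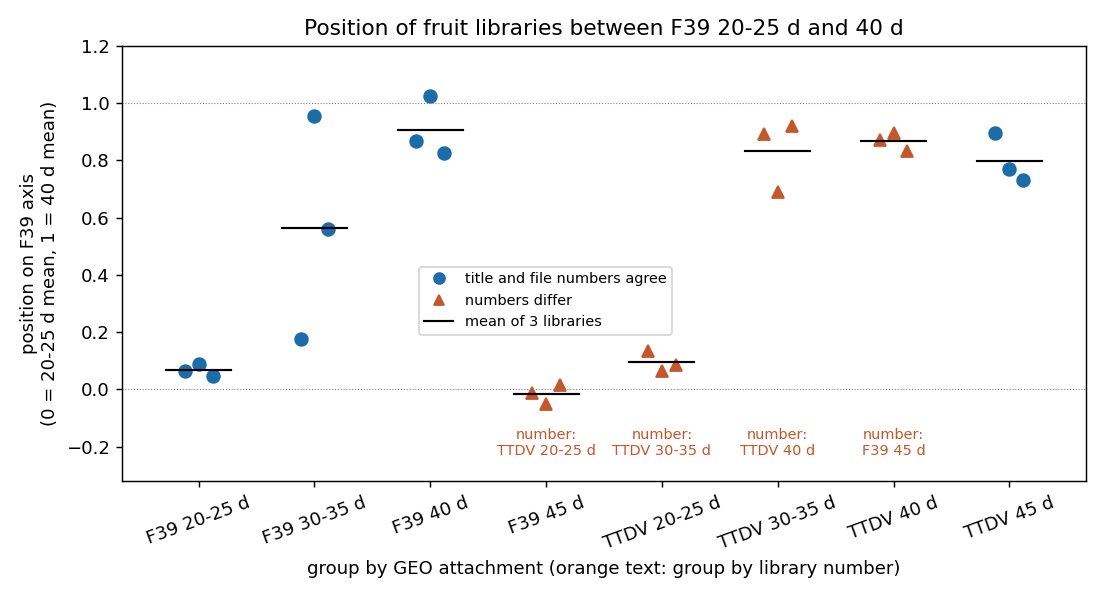
Position of each of the 24 fruit libraries between the means of F39 20-25 d (0) and F39 40 d (1), grouped on the horizontal axis by cultivar and days after flowering as attached in GEO; black lines are means of n = 3. Circles are libraries whose title and file numbers agree, triangles those whose numbers differ, with the group given by library number in orange text. The 3 libraries attached to F39 45 d lie between -0.052 and 0.016, and those of TTDV 45 d between 0.733 and 0.895.

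As attached in GEO, F39 fruit at 45 d lay nearest to the 20-25 d stage. The 3 libraries lay at -0.014, -0.052 and 0.016 on the scale from 20-25 d (0) to 40 d (1), and their median Spearman correlation across genes was 0.86 with F39 fruit at 20-25 d and 0.62 with F39 fruit at 40 d. MELO3C015762.2 and MELO3C013954.2, which had no count at 40 d, stood at 183.7 ± 99.3 and 125.4 ± 84.1 CPM (SD, n = 3 each), at least 1420-fold and at least 970-fold higher than at 40 d, with adjusted p = 2.02e-04 and 0.00188 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Without replicate 1 of 45 d the bound for MELO3C013954.2 was 644-fold. MELO3C030339.2 went from 769.5 ± 220.3 CPM (SD, n = 3) at 40 d to no count, at least 9265-fold lower, and MELO3C006254.2 from 548.8 ± 920.8 CPM (SD, n = 3) to no count, at least 6608-fold lower. Without replicate 2 of 40 d the bound for MELO3C006254.2 was 207-fold. Between 40 and 45 d 3026 genes were higher and 2829 lower, against 2252 and 2348 without replicate 1 of 40 d and 2301 and 2392 without replicate 3. With files matched by library number 484 were higher and 643 lower, and none of these 4 genes passed the threshold; the 3 libraries matched to F39 45 d lay between 0.832 and 0.896 on the same scale.

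In TTDV fruit, as attached in GEO, the largest part of the change fell between 20-25 and 30-35 d. The libraries lay between 0.063 and 0.134 on the F39 scale at 20-25 d, between 0.69 and 0.922 at 30-35 d, between 0.832 and 0.896 at 40 d and between 0.733 and 0.895 at 45 d. By library number the TTDV libraries lay between -0.052 and 0.016 at 20-25 d, between 0.063 and 0.134 at 30-35 d and between 0.69 and 0.922 at 40 d. MELO3C020432.2 held 0.048% ± 0.005 of counts at 20-25 d, 1.89% ± 0.357 at 30-35 d, 2.90% ± 0.802 at 40 d and 2.87% ± 0.41 at 45 d (SD, n = 3 each). By library number its shares in TTDV were 0.05% ± 0.023 at 20-25 d, 0.048% ± 0.005 at 30-35 d and 1.89% ± 0.357 at 40 d (SD, n = 3 each), so that the rise lay in the next step. As attached, its log2 fold change between 20-25 and 40 d was 5.82 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.23e-04). MELO3C029417.2 rose over the same interval from no count to 63.5 ± 23 CPM (SD, n = 3), at least 772-fold, and MELO3C016588.2 from no count to 26.4 ± 10.3 CPM (SD, n = 3), at least 322-fold. MELO3C005629.2 fell from 534.5 ± 858.4 CPM (SD, n = 3) to no count, at least 4180-fold, and MELO3C023361.2 from 309.8 ± 185.2 CPM (SD, n = 3) to no count, at least 2423-fold. Without replicate 1 of 20-25 d the bound for MELO3C005629.2 was 306-fold. The adjusted p values were 9.93e-04, 0.00658, 8.21e-04 and 0.00148 in that order (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Matched by library number, MELO3C016588.2 had a log2 fold change of -1.38 that did not pass the threshold, while the other 3 kept their direction and passed it.

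Over that interval 2275 genes were higher and 3175 lower in TTDV at 40 d, and 2736 and 2571 with files matched by library number. The step from 20-25 to 30-35 d gave 1898 higher and 2070 lower genes as attached, and 43 higher and 0 lower by library number, beside 2044 genes at an unadjusted p under 0.05. That total of 3968 became 2564 without replicate 1 of 20-25 d, 2267 (1178 higher, 1089 lower) and 2400 (1204 higher, 1196 lower) without replicates 1 and 3 of 30-35 d, and 1924 with only the 2 groups fitted. The step from 30-35 to 40 d gave 141 higher and 281 lower genes as attached, and 1898 higher and 2070 lower by library number. Its total of 422 fell in each of the 6 fits that left out 1 library, to between 57 without replicate 3 of 40 d and 268 without replicate 3 of 30-35 d, and was 1193 with DESeq2 and 254 without the filter. The step from 40 to 45 d gave 33 higher and 12 lower genes as attached, and 98 and 183 by library number. Its total of 45 became 9, 20 and 9 without replicates 1, 2 and 3 of 40 d, 19 and 23 without replicates 2 and 3 of 45 d, 147 with only the 2 groups fitted and 308 with DESeq2.

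At 20-25 d 26 genes were higher and 7 lower in TTDV than in F39, as attached in GEO. By library number 13 were higher and 15 lower, and as attached fewer were higher than lower with only the 2 groups fitted (5 and 8) and without replicate 1 of F39 (1 and 2). MELO3C026493.2 averaged 11.98 ± 3.21 CPM (SD, n = 3) in TTDV and had no count in F39, at least 148-fold higher. MELO3C032454.2 averaged 67.9 ± 38.5 CPM in TTDV and 0.146 ± 0.253 CPM in F39 (SD, n = 3 each), a log2 fold change of 8.68 (SE 1.29, adjusted p = 0.0112 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Both were also higher in TTDV by library number, where MELO3C032454.2 had a log2 fold change of 9.03. MELO3C026575.2 averaged 0.188 ± 0.326 CPM in TTDV and 40.8 ± 6.5 CPM in F39 (SD, n = 3 each), a log2 fold change of -7.91 (SE 1.35, adjusted p = 0.0156 by the same edgeR test with Benjamini-Hochberg adjustment). MELO3C035133.2 had a log2 fold change of -8.80 (SE 1.82, adjusted p = 0.0486 by edgeR with Benjamini-Hochberg adjustment). By library number these values were -3.83 and -2.54, and neither passed the threshold. As attached, the call for MELO3C035133.2 was lost in all 6 fits that left out 1 library, that for MELO3C026575.2 in 5, and those for MELO3C026493.2 and MELO3C032454.2 in 2 each. The log2 fold change of MELO3C032454.2 was 12.61 without F39 replicate 2, that of MELO3C026575.2 was -11.68 without TTDV replicate 3 and that of MELO3C035133.2 was -9.85 without TTDV replicate 2. The total of 33 became 3, 3 and 6 without replicates 1, 2 and 3 of F39, 8 and 186 without replicates 1 and 3 of TTDV, 13 with only the 2 groups fitted and 346 with DESeq2, beside 1682 genes at an unadjusted p under 0.05.

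At 30-35 d 215 genes were higher and 442 lower in TTDV, and 410 and 879 by library number. MELO3C035133.2 had no count in TTDV and 27.9 ± 24.9 CPM (SD, n = 3) in F39, at least 339-fold lower, and MELO3C008097.2 had no count in TTDV and 41.8 ± 48.9 CPM (SD, n = 3) in F39, at least 508-fold lower. MELO3C027442.2 averaged 15.7 ± 4.53 CPM (SD, n = 3) in TTDV and had no count in F39, at least 240-fold higher. The adjusted p values were 0.0131, 0.0254 and 0.0316 in that order (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and the 3 genes passed in the same direction by library number. Leaving out 1 library ended the call in 2 of 6 fits for MELO3C035133.2 and in 4 of 6 fits for each of the other 2 genes. Without F39 replicate 1 the bounds for MELO3C035133.2 and MELO3C008097.2 were 166-fold and 172-fold. The total of 657 became 166 and 1087 without replicates 1 and 2 of F39, 90 and 191 without replicates 1 and 3 of TTDV, 0 with only the 2 groups fitted and 1519 with DESeq2, beside 3029 genes at an unadjusted p under 0.05.

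At 40 d 484 genes were higher and 643 lower in TTDV, whereas 17 were higher and 11 lower by library number. MELO3C005555.2 averaged 73.9 ± 25.2 CPM in TTDV and 0.837 ± 0.93 CPM in F39 (SD, n = 3 each), a log2 fold change of 6.11 (SE 1.27, adjusted p = 0.00783 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MELO3C004222.2 had no count in TTDV and 407 ± 637 CPM (SD, n = 3) in F39, at least 3183-fold lower. Without F39 replicate 2 that bound was 314-fold, and the call was lost without TTDV replicate 1 and without TTDV replicate 3. For MELO3C005555.2 the log2 fold change was 7.43 without F39 replicate 3. By library number neither passed the threshold, with log2 fold changes of 2.96 for MELO3C005555.2 and -11.21 for MELO3C004222.2. The total of 1127 became 532 and 425 without replicates 1 and 3 of F39, 474, 510 and 236 (122 higher, 114 lower) without replicates 1, 2 and 3 of TTDV, 720 without the filter, 1998 with only the 2 groups fitted and 2081 with DESeq2.

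At 45 d 2932 genes were higher and 3143 lower in TTDV, and 33 and 12 by library number. MELO3C030339.2 averaged 261.4 ± 265.7 CPM and MELO3C002311.2 208.7 ± 116.6 CPM in TTDV (SD, n = 3 each), with no count in F39, at least 3147-fold and at least 2513-fold higher. MELO3C023027.2 averaged 1025 ± 376 CPM and MELO3C017297.2 431.2 ± 424.2 CPM in F39 (SD, n = 3 each), with no count in TTDV, at least 8150-fold and at least 3429-fold lower. The adjusted p values were 7.17e-04, 1.71e-04, 3.9e-05 and 1.23e-04 in that order (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). By library number none of the 4 passed the threshold, and the log2 fold changes of MELO3C030339.2, MELO3C002311.2 and MELO3C023027.2 were 0.11, -0.19 and -8.75. As attached, the bound for MELO3C030339.2 was 1301-fold without TTDV replicate 1, and that for MELO3C017297.2 was 1658-fold without F39 replicate 2.

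**Figure D3:**
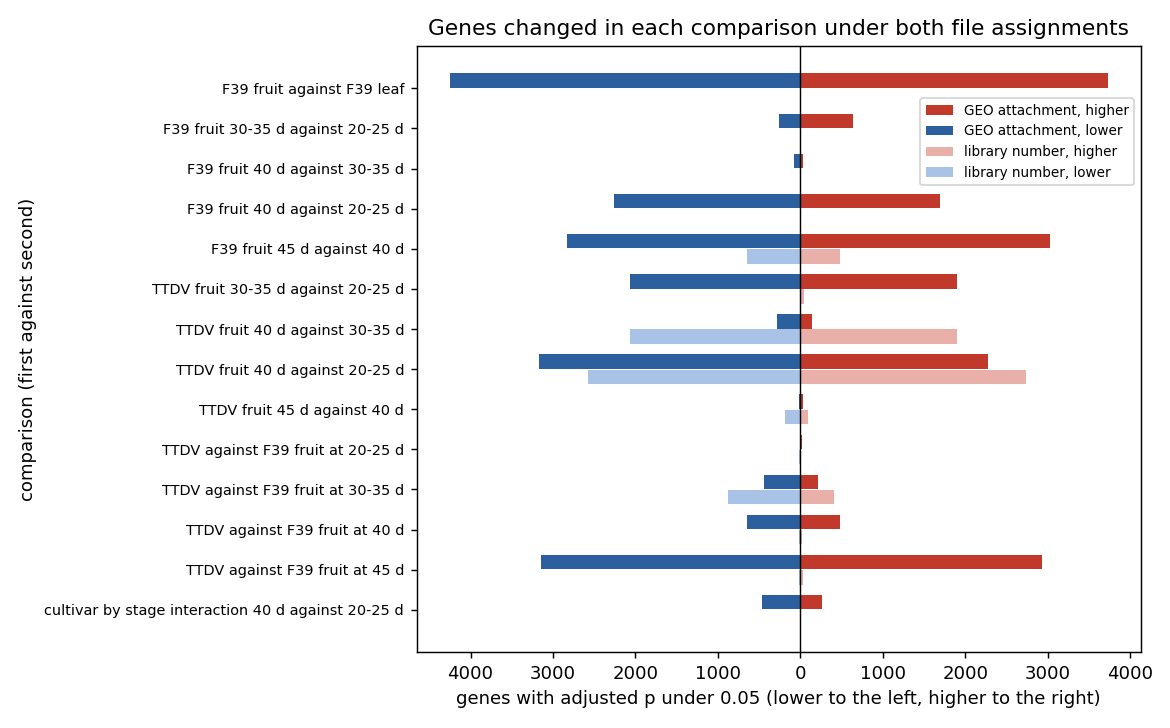
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 by edgeR's quasi-likelihood test in each comparison, with genes lower in the first-named group to the left of 0 and genes higher to the right. Dark bars follow the attachment in GEO and pale bars the library number; the first 4 comparisons use only libraries whose numbers agree and have dark bars only, and the interaction has 729 genes as attached and 0 by library number.

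The change from 20-25 to 40 d could be compared between the cultivars without shared libraries. Both lists still came from 1 model with the same filter and gene-wise dispersion estimates. The counts given for independent lists are therefore a reference only. Of the 1692 genes higher at 40 d in F39, 858 were also higher in TTDV as attached in GEO, where independent lists would share 254.4, and 86 were lower. Of the 2262 genes lower at 40 d in F39, 1439 were also lower in TTDV, where independent lists would share 474.7, and 25 were higher. By library number 1196 higher and 1568 lower genes were shared, against 306 and 384.4 for independent lists, and 3 and 9 went the opposite way. Across the 15130 genes, which are not independent replicates, Pearson's r of the fold changes was 0.566 as attached and 0.716 by library number.

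The difference between the cultivars in this change was tested as an interaction. As attached in GEO, the signed log2 change was more positive in TTDV than in F39 for 267 genes and more negative for 462. These calls are by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The sign does not tell in which cultivar a gene changed more. By library number edgeR called 0 genes, beside 1414 at an unadjusted p under 0.05 and 115 by DESeq2. The total of 729 became 367 and 429 without F39 20-25 d replicates 1 and 3, 413 without F39 40 d replicate 3, 342 without TTDV 20-25 d replicate 1, 445, 414 and 333 without TTDV 40 d replicates 1, 2 and 3, and 1425 with DESeq2.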

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

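The count of separating genes, the comparison with a further set of F39 45 d libraries, the tests of a swap and of depth, and the test of the library numbers 59 to 64 were chosen only after the results they concern were seen; the other splits of the libraries and the spread off the axis were set before.

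As attached in GEO, the change from 20-25 to 40 d differed between the cultivars in 729 genes by the interaction test, which is why it is listed here. Among the 60 splits drawn for this test, 1 gave as many genes, the real split with 735 in a fit of the compared libraries. The highest of the others gave 382. The share with as many genes was under 0.05. Almost all of the other splits mixed the cultivars within a group, which widens the spread there wherever the cultivars differ. Their lower counts therefore cannot decide about chance. The share concerns the assignment of these libraries only, since the labels do not say whether they came from separate plants. For fruit against leaf 1 of 100 splits gave as many genes, the real split with 6313 against a highest other of 11. These fits had 1 group of 3 libraries and 1 of 9, the fruit stages being pooled. Every other split left leaf libraries in the group of 9, which widens the spread within it, so the low counts cannot decide about chance.

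The 3 against 3 comparisons have 10 splits each, too few for a share under 0.05. In 9 of them 1 split, the real one, gave as many genes. The real and highest other counts were 3984 and 0 for F39 at 40 against 20-25 d, 4877 and 0 for F39 at 45 against 40 d, 1924 and 0 for TTDV at 30-35 against 20-25 d, 485 and 0 for TTDV at 40 against 30-35 d, 4660 and 0 for TTDV at 40 against 20-25 d, 147 and 2 for TTDV at 45 against 40 d, and 13, 1998 and 5139, each against 0, for the cultivars at 20-25, 40 and 45 d. For F39 at 30-35 against 20-25 d, F39 at 40 against 30-35 d and the cultivars at 30-35 d, the real split and every other gave 0 genes, so that 10 of 10 gave as many.

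The libraries attached to F39 45 d resembled fruit of 20-25 d, and the interaction of 729 genes was 0 with files matched by library number. Files attached to the wrong samples may account for this: by library number 13 genes separated all 12 F39 from all 12 TTDV fruit libraries, against 0 as attached and at most 2 under the other 2 assignments that keep the undisputed cultivars. Among these genes MELO3C016167.2 ranged from 191.5 to 3400 CPM in F39 and from 0.526 to 155.2 CPM in TTDV, and MELO3C032454.2 averaged 0.079 ± 0.152 CPM in F39 and 43.3 ± 42.7 CPM in TTDV (SD, n = 12 each); these examples were picked after their values were seen, and setting the F39 20-25 and 30-35 d triplets and those attached to F39 45 d and TTDV 20-25 d against the other 4 gave 145 separating genes. This partition gave the most separating genes of the 35 possible. Under the library numbers it sets fruit of 20-25 and 30-35 d against later fruit in both cultivars. As attached it instead puts F39 45 d with the earlier fruit and TTDV 30-35 d with the later. The positions of the same libraries already show this, so the 145 genes are not separate evidence. By position, F39 fruit at 45 d with the profile of 20-25 d fruit cannot be told apart from wrongly attached files. The highest of the 3 libraries lay at 0.016, and there is no further set of F39 45 d libraries. The 13 genes put the files attached to F39 45 d with TTDV and those attached to TTDV 40 d with F39. A 20-25 d profile of F39 45 d fruit would not by itself give the latter. The genes were found in these same libraries, however, and a partition that mixes the cultivars under both assignments gave 9. The comparisons of the 12 libraries rest on which assignment holds.

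The 3 F39 30-35 d libraries were spread from 0.177 to 0.954 between the 20-25 and 40 d stages. A depth difference is argued against by a ratio of largest to smallest total of 1.09, lower than the 1.88 and 1.42 of the neighbouring groups. A swap with a library of either neighbouring group stays open: no 20-25 d library lay above 0.09 and no 40 d library below 0.825, but the TTDV 30-35 d libraries lay between 0.69 and 0.922 as attached and between 0.063 and 0.134 by library number, so that a swapped library of 30-35 d need not stand out in those groups. Fruits at different points of one course within the 30-35 d window are a candidate explanation. The spread off the axis was 0.792 (SD of log2 CPM), higher than in the F39 20-25 d (0.591), F39 40 d (0.709) and TTDV 45 d (0.654) groups. It was within the bound only because that bound, set beforehand, allowed a margin above the highest of these. On the axis lay 38% of the variation, so the larger part lay off it. A single wrong label within the group and a difference in growing conditions stay open and were not tested.

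Matched by library number, F39 fruit at 45 d differed from 40 d in 1127 genes. A separate run of the libraries numbered 59 to 64 may contribute, since these hold all 45 d libraries of both cultivars: 93.6% of the genes called in F39 moved the same way in TTDV, against 68.1% of the other genes, and 147 were also called there. A shared change between 40 and 45 d would give the same, and the design confounds stage with library number, so the run and the stage cannot be told apart.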

How the results depend on the processing

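The fit with the 15 libraries whose numbers agree, the fruit mean without 30-35 d, and DESeq2 on the interaction by library number were chosen after seeing the data; the other alternatives were set before. Counts of called genes stayed within 1.5 times in all 14 comparisons with median-of-ratios scaling and with the stricter filter, in 11 without the filter, in 6 with DESeq2 and in 7 with only the groups compared, and for fruit against leaf without 30-35 d. The cause of the other changes was not tested. Fewer libraries entered the smaller fits, but with only the groups compared counts rose as well as fell. Examples are 45 to 147 for TTDV 45 against 40 d and 888 to 0 for F39 30-35 against 20-25 d. DESeq2 gave 1794 genes for F39 30-35 against 20-25 d, 740 for F39 40 against 30-35 d, 1193 for TTDV 40 against 30-35 d, 308 for TTDV 45 against 40 d, 346, 1519 and 2081 for the cultivars at 20-25, 30-35 and 40 d, and 1425 for the interaction. Only the groups compared gave 0 for F39 30-35 against 20-25 d, 0 for F39 40 against 30-35 d, 1924 for TTDV 30-35 against 20-25 d, 147 for TTDV 45 against 40 d, and 13, 0 and 1998 for the cultivars at 20-25, 30-35 and 40 d. No filter gave 70 for F39 and 254 for TTDV at 40 against 30-35 d, and 720 for the cultivars at 40 d. The 15 libraries gave 490 for F39 30-35 against 20-25 d and 13 for 40 against 30-35 d. Files matched by library number gave 1127 for F39 45 against 40 d, 43, 3968 and 281 for the TTDV steps to 30-35, 40 and 45 d, 1289, 28 and 45 for the cultivars at 30-35, 40 and 45 d, and 0 for the interaction (115 with DESeq2).

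Leaving out 1 library in turn gave 6801 to 8079 genes for fruit against leaf, 68 to 2222, 0 to 623 and 4493 to 5044 for the F39 steps to 30-35, 40 and 45 d, 2594 to 2976 for F39 40 against 20-25 d, 2267 to 4051, 57 to 268 and 9 to 37 for the TTDV steps, 4031 to 5202 for TTDV 40 against 20-25 d, 3 to 186, 90 to 1087, 236 to 779 and 4706 to 5497 for the cultivars at 20-25, 30-35, 40 and 45 d, and 333 to 992 for the interaction. The 52 calls of genes picked by the naming rule in 13 comparisons held with median-of-ratios scaling, and 51 with DESeq2, which gave no adjusted p for 1; in the fits without 1 library 253 held and 83 did not. By library number 10 held, 19 kept their direction or lay at 0 without passing, and 7 reversed, none passing: in TTDV MELO3C005629.2 at 3.49 for 30-35 against 20-25 d, MELO3C035133.2 at -3.38 and MELO3C016167.2 at -2.40 for 40 against 30-35 d, MELO3C032454.2 at -0.29 and MELO3C016167.2 at 2.36 for 45 against 40 d, and MELO3C016588.2 at -1.38 for 40 against 20-25 d, and between the cultivars at 45 d MELO3C002311.2 at -0.19. The check of attachment found 2 genes at 2 CPM in place of 0; its other detection minimum gave no value, as no gene was defined. The 4 alternatives for gene lists were not run, because no gene names were paired with IDs. No paired analysis was possible because the labels give the groups no shared replicate numbers. Depth limits the genes at no count, whose folds are lower bounds.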

Other observations

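The comparison of leaf-high genes below was chosen only after its result was seen.

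Differences between leaf and fruit were set beside the change with fruit age in F39. To keep the libraries apart, leaf was compared with fruit at 30-35 d, and the change was read between 20-25 and 40 d. Separate libraries do not make the choice of genes independent of that change. The 30-35 d level, at a mean position of 0.564 on the scale from 20-25 to 40 d, already holds part of it. How far this moved the values below was not tested. The 3304 genes higher in leaf had a median log2 change of -0.41, with 699 falling (21.2%) and 345 rising (10.4%) by edgeR's quasi-likelihood test. The 3469 genes higher in fruit had a median of 0.19, with 417 falling (12%) and 658 rising (19%). Over all genes tested 15% fell and 11.2% rose.

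The median of -0.41 lay below all 10000 random lists of the same size matched on mean expression, whose medians ran from -0.26 to -0.01, while the median of 0.19 for fruit-high genes lay above all of theirs (-0.03 to 0.11). The random lists describe these libraries only: genes that vary together are not independent, so the ranges give no p-value for the difference. They were matched on mean expression alone. A tie between the choice of genes at 30-35 d and the change could therefore place the medians outside them. The genes carry no names here, so the processes involved were not examined, and the 30-35 d libraries used to choose the genes were themselves spread between the neighbouring stages.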
